A study of Drosophila melanogaster with 12 samples.

How the data were processed

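The series measured messenger RNA in adult heads of y w; tim01 fruit flies (Drosophila melanogaster) with Affymetrix DrosGenome1 arrays. The tim01 mutation removes the function of timeless, a core gene of the circadian clock. Flies were kept for 3 days in 12 h of light and 12 h of darkness. They were then collected every 4 h over 1 more such day (LD, named by zeitgeber hour as ZT2 to ZT22) and over the following day in constant darkness (DD, named by the corresponding hour as CT2 to CT22). Per the labels, a sample held the heads of about 100 to 200 flies. Frozen flies were broken up and heads were separated with sieves, and cRNA labelled with biotin was made from 25 µg of RNA. The numeral in the series title calls this time course 2. No other time course and no wild-type sample was analysed here.

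The deposited table holds log2 values made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes between arrays by quantiles and summarises the probes of a probe set on the log2 scale. Its version and the set of arrays it was run on are not given in the sources used here. The array medians lay between 4.00 at CT2 and 4.10 at ZT6 and ZT14, so the 12 columns did not have identical distributions. The quantile step was therefore run again over these arrays as an alternative. Arrays carry no read depth, and their number limits the precision. None of the 66 pairs of arrays held identical values. Pearson correlations across probe sets lay between 0.985 and 0.996.

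Of 14010 probe sets, 44 controls were left out and 13966 were tested. The platform annotation gave 1 gene symbol for 12442 of them, several for 327 and none for 1197. Probe sets with several symbols or none were tested but not named here. Checking symbols through Entrez identifiers changed 0 of them. The named probe sets covered 10843 genes, and 1209 genes had more than 1 probe set. Such a gene is represented by the probe set with the highest mean over all arrays. Locus tags in brackets come from the RefSeq gene table.

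The 12 arrays were placed in 4 groups of 3: LD light (ZT2, ZT6, ZT10), LD dark (ZT14, ZT18, ZT22), DD subjective day (CT2, CT6, CT10) and DD subjective night (CT14, CT18, CT22). There was 1 array per time. The 3 arrays of a group are therefore not replicates of 1 condition, and their spread includes any change within the phase. The p-values measure only the spread among these arrays. The LD day always preceded the DD day, so lighting cannot be separated from the day of collection and the age of the flies.

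Group differences were tested with limma 3.58.1 in R 4.3.3. Means of the 4 groups were fitted to all 12 arrays with 8 residual degrees of freedom, and 6 contrasts were taken with moderated, two-sided statistics. Daily change was fitted as a cosine and a sine term with a period of 24 h. It was fitted separately for LD and DD with 6 residual degrees of freedom, and as 1 curve shared by both days, and tested with limma's moderated F statistic. Amplitude is the distance from the mean to the peak on the log2 scale. Benjamini-Hochberg adjustment covered all probe sets of a comparison, with a threshold of 0.05. A difference of the harmonic between the days was added after the data were seen.

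The design, the gene lists and the rule for naming genes were set before the data were examined. The rule named the core clock list and y. In each contrast it named the 8 largest rises and the 8 largest falls among genes past the threshold, or the 5 smallest p-values where none passed. In each harmonic fit it named the 12 largest amplitudes past the threshold, or the 5 smallest p-values. In each gene list it named the 4 members with the smallest p-values. The transcripts of w and to, which the rule also listed, are not named by the annotation used here.

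The 28 gene lists covered 19 pathways and 9 cell types or tissues: core clock, clock output candidates, phototransduction and visual cycle, screening pigment, neuronal activity response, heat shock and chaperones, DNA repair and photolyase, antimicrobial and immune response, digestive enzymes, fasting and feeding response, fatty acid and sterol synthesis, glycolysis, detoxification, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome, cuticle proteins, odorant binding proteins, neuropeptides, neuron, glia, head fat body, thorax muscle, midgut, female germline and follicle, male germline and accessory gland, sex marker, and hemocyte. Members without a probe set of their own were left out, so that 14 names of the heat shock list were measured and 14 were not, and 24 and 30 of the immune list. Their shifts were tested with camera at its preset correlation of 0.01 between genes, adjusted over 168 tests of 28 lists in 6 contrasts. The same tests were repeated with an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction. No call of any list held with an estimated correlation or by fry's directional test. Fry's mixed test, for changes in either direction, was adjusted over the same tests.

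A body-tissue score was formed after the data were seen. For each array it is the mean of the medians of the midgut, male germline and accessory gland, and thorax muscle lists, with each gene taken relative to its own mean over the arrays. Correlations between list medians over the 12 arrays carry p-values from 100000 permutations, adjusted over 21 pairs.

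The fits were tested on simulated arrays with the real means and spreads, 13966 probe sets, 100 changed probe sets of each of 2 sizes in a run, and changes in both directions. In the LD light against dark contrast, 84 of 100 changes of 0.5 log2 and 98 of 100 changes of 1 log2 were recovered, with 5.7% of calls false. For the DD subjective day against night contrast these were 78, 98 and 4.3%. For the difference between both contrasts they were 49, 97 and 6.4%. The LD harmonic recovered 91 of 100 amplitudes of 0.5 and the DD harmonic recovered 90. The permutation test of the harmonics pools the permuted values of all probe sets. Within a day its 60 orders include the real one, so each observed value is also in its own null. This limits how small an adjusted p can become. On the simulated arrays the smallest adjusted p by this test was 0.0194 in LD, 0.0315 in DD and 4.76e-05 for the shared curve. With 100 simulated changes of each size, the permutation test recovered 4, 37 and 75 amplitudes of 0.5, 1 and 2 in LD. It recovered 6, 33 and 72 in DD, and 96, 98 and 100 of the shared curve. The simulated arrays had independent noise and no shared tissue component. A list of 14 genes shifted by 0.3 was called in all 4 contrasts that held the shift, and 0 of the other 164 list tests were called.

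Alternatives fixed before the data were examined were quantile normalization, centring each array on its median, restriction to probe sets at or above the median mean level, a trended robust prior, array weights, a linear trend over collection hours, 1 probe set per gene, a threshold of 0.10, a fit of only the arrays compared, clock hour as a block, permutation of the arrays within a day, and leaving out each array in turn. The trend was not fitted to contrasts between days, which it cannot be separated from. Within a day the light and dark phases, or subjective day and night, also follow each other in time. The trend is therefore partly confounded with them and lowers the precision of a contrast between them. A different offset before taking logs did not apply because the deposited values were already on the log2 scale. Added after the data were seen were the body-tissue score as a covariate and fits without the 3 subjective-night arrays.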

Results

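RNA was profiled at 12 times in heads of y w; tim01 flies, which lack a working circadian clock because timeless is mutated. The time course ran over 1 day of light and darkness and then 1 day of constant darkness, with 6 arrays on each day. The comparisons address which transcripts still change over the day without a clock, and whether such change needs the light cycle. Values are RMA values on the log2 scale. Errors are standard errors (SE) of the limma fit or standard deviations (SD) over the 3 arrays of a group.

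Transcripts of the clock itself showed little movement. The values of per, whose product represses the clock's activators, stayed between 4.81 and 5.30 over the 12 arrays, and those of tim stayed between 6.44 and 6.78. The transcription factor genes vri and Pdp1 ranged over 0.43 and 0.57, and Clk, whose mean of 2.65 lay below the lower quartile of every array, ranged over 0.64. The photoreceptor gene cry ranged over 0.28. None of the 13 measured core clock genes passed the threshold in any contrast or harmonic fit. The smallest adjusted p of a clock gene was 0.292, for the neuropeptide gene Pdf in the DD subjective day against night contrast, with a difference of 0.21 (SE 0.071). Adjusted over the list alone, 1 core clock gene passed in the LD harmonic. The member with the smallest p there was slmb, an F-box gene of the protein degradation machinery, with an amplitude of 0.21 (SE 0.05). The mean of slmb, 2.94, was low, within the range of the lower quartiles of the arrays (2.88 to 2.97). Its fitted peak was at hour 22.5 in LD and 12.8 in DD. The body colour gene y, mutated in this strain, ranged over 0.23.

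**Figure D1:**
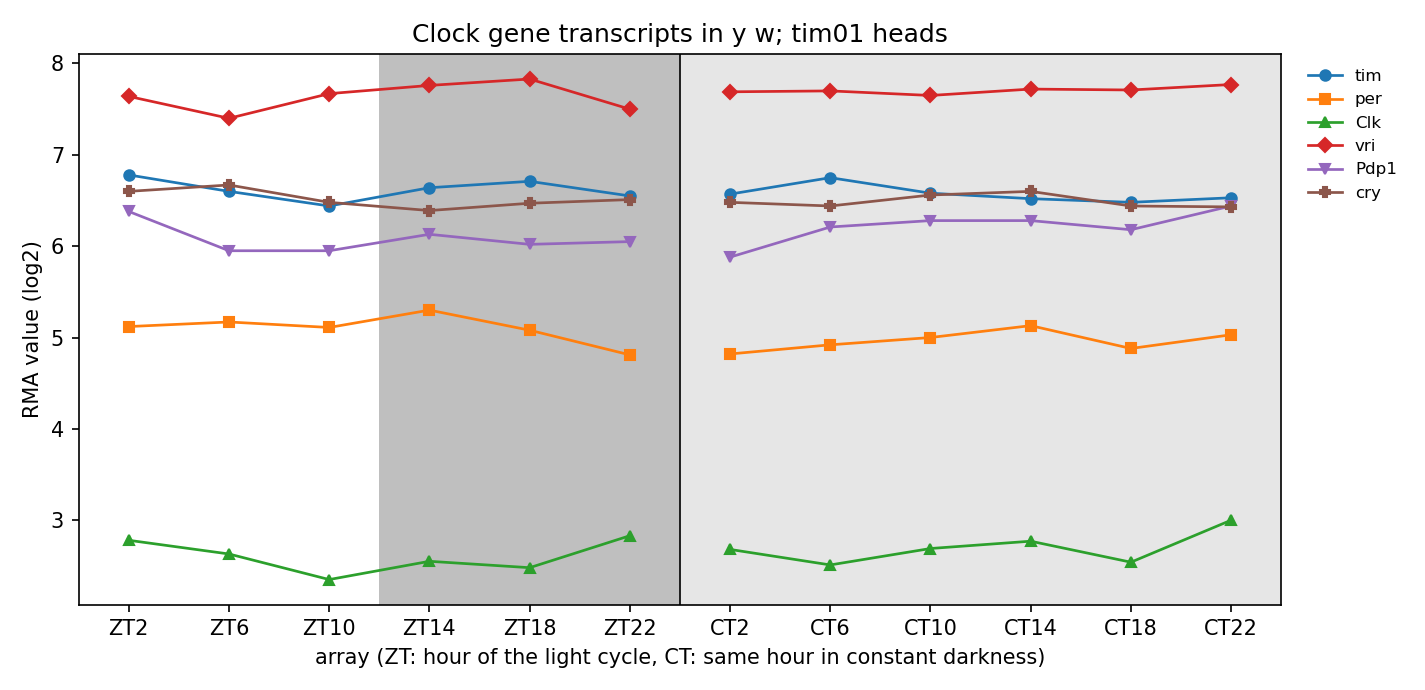
RMA values (log2, vertical axis) of 6 clock genes on the 12 arrays (horizontal axis); each point is 1 array, dark grey marks the dark phase of the LD day and light grey the DD day. Each line stays within a range of 0.64 or less, that of Clk.

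In the LD day, 4 probe sets differed between the light and the dark phase, all lower in light. Drat (CG1600), which encodes a protein with an alcohol dehydrogenase domain, had a mean of 6.90 ± 0.24 in light and 7.64 ± 0.23 in darkness (SD, n = 3 arrays each), a difference of -0.74 (SE 0.117, limma adjusted p = 0.0474). Pka-C3 (CG6117), a catalytic subunit gene of protein kinase A, differed by -0.50 (SE 0.072, adjusted p = 0.0397). Sirup (CG7224), an assembly factor gene of mitochondrial complex II, differed by -0.46 (SE 0.07, adjusted p = 0.0397). The other was a probe set of M7BP, a myosin-binding protein gene, at -0.77 (adjusted p = 0.0397); it was not that gene's highest probe set and was named after its values were seen. The body-tissue score, formed from midgut, male reproductive and thorax muscle markers, was -0.20 ± 0.07 in LD light and -0.04 ± 0.24 in LD dark (SD, n = 3).

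Gene lists shifted by small amounts between light and darkness in LD. Head fat body genes had a median difference of 0.08 (camera adjusted p = 0.0437), and cuticle proteins of 0.06 (0.00156). Within the fat body list, the storage protein gene Lsp2 was at 0.64 (SE 0.106, adjusted p = 0.0597), and it passed when adjusted over the list alone. Male germline and accessory gland genes were lower in light with a median of -0.22 (0.000153), digestive enzymes with -0.14 (0.000519) and thorax muscle genes with -0.10 (0.0113). With an estimated correlation these 5 lists had adjusted p = 0.404 or more. Of these 5 calls, 4 were lost without single arrays and the cuticle call was kept without any: without ZT22, the LD array with the highest body-tissue score (0.17), the male list was at -0.06 (adjusted p = 0.384), digestive enzymes at -0.09 (0.313), thorax muscle at -0.08 (0.0748) and cuticle proteins at 0.04 (0.0285). Without ZT2 the male list was at -0.14 (adjusted p = 0.0695), digestive enzymes at -0.09 (0.093) and head fat body at 0.10 (0.132), and without ZT14 the male, digestive and muscle lists were at -0.39, -0.29 and -0.19. Without ZT18 the muscle list was at -0.08 (adjusted p = 0.0722) and head fat body at 0.04 (0.0799), without CT2 head fat body was at 0.08 (0.0637), and without ZT10 it was at 0.05 and the muscle list at -0.06. Phototransduction and visual cycle genes went in different directions. Over that list alone, 3 of 31 genes were higher and 3 lower in light, and over all probe sets 0 passed. The light-sensitive channel gene trpl was at 0.43 (SE 0.107, adjusted p = 0.378), and rdgC, which encodes a rhodopsin phosphatase, at -0.60 (SE 0.139, adjusted p = 0.329). Of the clock output candidates, 1 of 11 was higher and 3 lower over the list alone, with Slob at -0.54 (SE 0.197) and Usp8 at 0.42 (SE 0.142). The count of 4 became 0 with quantile normalization, with a trend over collection hours, with only the 6 LD arrays, without the 3 subjective-night arrays, and without any 1 of ZT6, ZT10, ZT18, CT2, CT6, CT14, CT18 or CT22. The count was 1 without ZT2 and 8 without ZT14. The trend is partly confounded with the phases of a day, so the 0 with it cannot tell a steady change from a phase difference.

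A 24 h harmonic in LD was called for 9 probe sets, among them 7 genes named by the rule. The largest amplitude was that of t (tan, CG12120), which encodes an enzyme that regenerates histamine, the photoreceptor transmitter. Its value was 6.66 at ZT2, 5.47 at ZT14 and 6.51 at ZT22, with an amplitude of 0.61 (SE 0.062, adjusted p = 0.00537) and a fitted peak at lights-on. Its lowest value was on ZT14, the array with the largest 3′ to 5′ differences of the eIF-4a and GAPDH controls (3.70 and 2.58) and the lowest spike-in mean (8.32). Without ZT14 the amplitude of t was 0.58 and its adjusted p was 0.0582, and 2 of the 7 genes passed, Drat and rdhB. Slob, which encodes a protein that binds the Slowpoke potassium channel, fell from 7.78 at ZT2 to 6.79 at ZT6 and stood at 8.04 at ZT18 (amplitude 0.60, SE 0.078, adjusted p = 0.0312). Drat peaked at hour 19.2 with an amplitude of 0.58 (adjusted p = 0.00521), and rdhB, a retinol dehydrogenase gene that acts in making the visual chromophore, at hour 19.1 with 0.39 (0.0312). The endocytic adaptor gene lqf peaked at hour 23.2 with an amplitude of 0.50 (0.016) and CG7135 at hour 23.6 with 0.35 (0.0364). Lsp2 went the other way, with a peak at hour 7.2 and an amplitude of 0.48 (0.0312). The other called probe sets were that of M7BP, at 0.59, and 1 with no gene symbol. A second probe set of Slob, with a lower mean of 5.44, had an amplitude of 0.07.

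In constant darkness the same 7 genes had DD amplitudes between 0.05 and 0.14, none past the threshold. The value of t lay between 6.60 and 6.87 on all 6 DD arrays, and that of Drat between 7.43 and 7.59. The difference of the harmonic between LD and DD, tested after the data were seen, passed for 0 probe sets by limma's moderated F test, with 1060 at an unadjusted p under 0.05. Drat had the smallest adjusted p, 0.13, with a difference amplitude of 0.61 (SE 0.076), followed by lqf with 0.57 (adjusted p = 0.164), t with 0.61 (0.164), CG7135 with 0.43 (0.177) and Sirup with 0.48 (0.177). These differences therefore did not pass the test.

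Visual genes also had LD harmonics when the phototransduction and visual cycle list was taken by itself. Adjusted over the list alone 10 of 31 passed, and over all probe sets 0 did. The smallest p-values belonged to rdgC (amplitude 0.50, SE 0.075, peak at hour 18.3, adjusted p = 0.066), ninaB, which encodes the oxygenase that makes retinal (0.26, SE 0.045, hour 13.2), trpl (0.35, SE 0.061, hour 7.4) and the photoreceptor dehydrogenase gene Pdh (0.28, SE 0.056, hour 19.3). The same list had 0 passing genes over the list alone in the DD harmonic and 1 in the difference between the days. In DD the smallest p of the list was that of trpl (amplitude 0.23, SE 0.061, hour 5.7, adjusted p = 0.222). A change of trpl in darkness was therefore neither called nor excluded. The other genes named here, rdgC, ninaB and Pdh, were not among the 4 members with the smallest p in DD. Over their lists alone, 4 of 11 clock output candidates and 4 of 19 screening pigment genes passed in LD, and Rab32 had the smallest p of the pigment genes (amplitude 0.34, SE 0.05, hour 15.4). The LD count was 0 with only the LD arrays, without the subjective-night arrays, and by permutation of the arrays within the day, a test that found 4 of 100 simulated amplitudes of 0.5. The count was 4 with quantile normalization, 16 with median centring, 28 above the median mean level, 38 with the trended robust prior and 23 with array weights; it was 3 without ZT6, ZT18 or CT6, 4 without CT10 or CT14, 5 without CT2, CT18 or CT22, and 15 without ZT10.

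**Figure D2:**
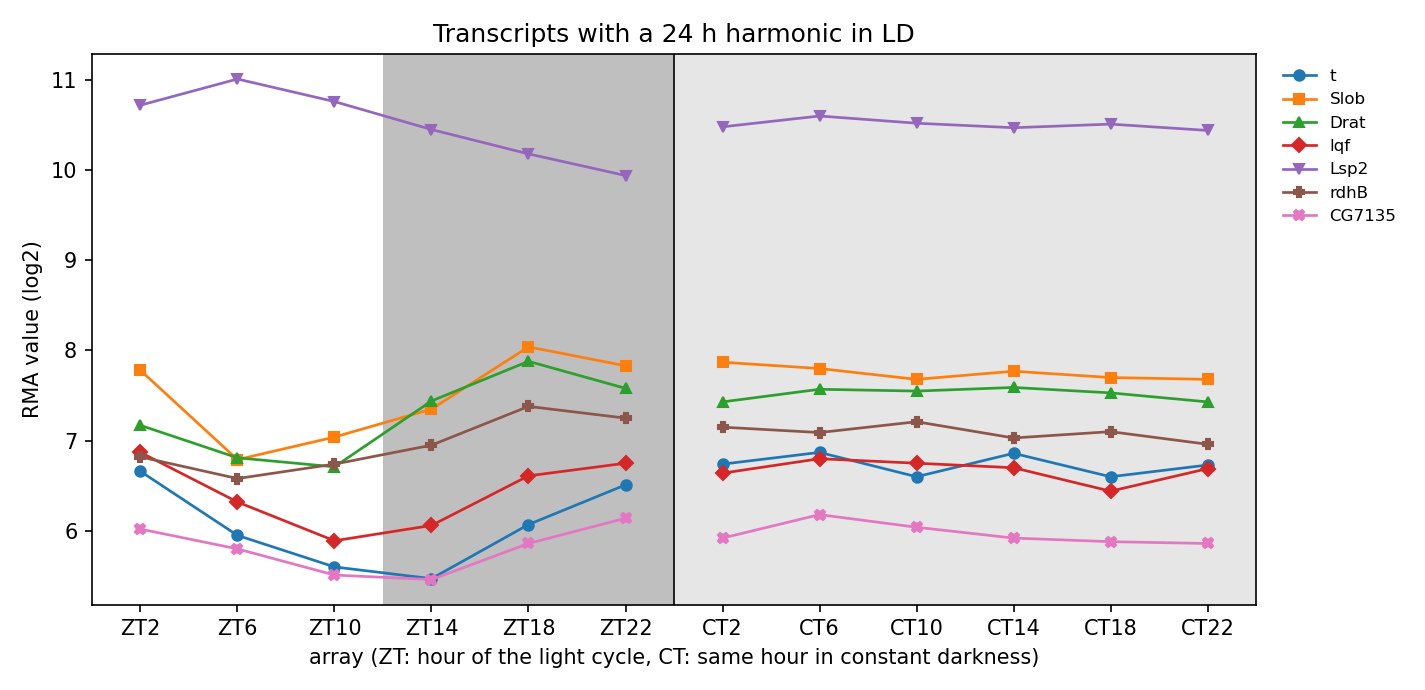
RMA values (log2, vertical axis) of the 7 named genes with a 24 h harmonic in LD on the 12 arrays (horizontal axis); each point is 1 array, dark grey marks the dark phase of the LD day and light grey the DD day. The line of t moves from 6.66 to 5.47 within the LD day and stays between 6.60 and 6.87 in DD.

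In constant darkness, 194 probe sets differed between subjective day and subjective night, 7 higher and 187 lower in the day. The largest falls were in digestive proteases. Jon99Fi (CG18030) was at 2.44 ± 1.01 by subjective day and 5.58 ± 0.86 by subjective night (SD, n = 3 arrays each). The difference was -3.15 (SE 0.642, adjusted p = 0.0234). The subjective-day mean of Jon99Fi lay below the lower quartile of every array, so the size of this difference is uncertain. The trypsin genes alphaTry and betaTry differed by -3.07 (SE 0.672, adjusted p = 0.0337) and -2.85 (SE 0.657, 0.0458). The protease genes yip7, Jon25Biii, Bace and Jon99Fii differed by -2.67, -2.65, -2.55 and -2.44. Acp53C14a, a male accessory gland protein gene, differed by -2.51 (SE 0.588, adjusted p = 0.0494). The 5 named genes that were higher in the day changed less. They were CG9150 (0.40, SE 0.075), CG18428 (0.33), CG34229 (0.33), CG9902 (0.32) and the sodium channel family gene ppk21 (0.24). A second probe set of CG18428 was at 0.12 and did not pass.

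Genes of the midgut, male reproductive and thorax muscle lists were lower together. Of the 172 named genes past the threshold, 32 belonged to these lists or to the digestive enzymes. Of 43 digestive enzymes, 15 were lower in the subjective day (28 adjusted over the list alone), with a median of -0.42; the sugar-cleaving enzyme gene Mal-A1 was at -1.67 (SE 0.192, adjusted p = 0.00103). Of 14 midgut genes, 7 were lower (10 over the list alone), with a median of -0.75. Of 24 male germline and accessory gland genes, 13 were lower (21 over the list alone), with a median of -0.82. Among them were the seminal fluid gene Acp36DE (-1.91, SE 0.307, adjusted p = 0.00708) and the sperm gene dj (-1.38, SE 0.24). The mean of dj over all arrays, 2.58, lay below the lower quartile of every array. Of 17 thorax muscle genes, 4 were lower (11 over the list alone), with a median of -0.29, among them the flight muscle genes Act88F (-1.31, SE 0.228, adjusted p = 0.0105) and fln (-1.02, SE 0.191). Camera adjusted p-values were 2.33e-25, 1.86e-12, 6.54e-28 and 9.34e-12 in that order, and for each of the 4 lists adjusted p = 0.328 with an estimated correlation. Of the midgut genes, 11 also belong to the digestive enzyme list. The female germline and follicle list had a median of -0.005.

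The body-tissue score was -0.18 ± 0.20 in the subjective day and 0.42 ± 0.07 in the subjective night (SD, n = 3 arrays each; two-sided exact permutation p = 0.1, the smallest that 3 arrays against 3 can give). With this score as a covariate the count was 0, not 194, and the 187 lower probe sets had a median of -0.16 (median SE 0.18) in place of -0.82 (0.14). The score was formed after the data were seen and separates these groups. With it the standard error over all probe sets was larger by a median factor of 1.91, so the 0 does not identify a cause. The count was also 0 with a trend over collection hours, 82 above the median mean level and 101 with the trended robust prior. Because that trend is partly confounded with subjective day and night, the 0 with it cannot tell a steady change from a phase difference. Without CT2 the count was 34, without CT6 40, without CT14 72 and without CT18 44.

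Over the 12 arrays the medians of these lists moved together. Midgut and male reproductive medians had r = 0.95 (permutation p = 2e-05, adjusted 0.00014; Spearman's rho = 0.91, p = 8e-05, adjusted 0.00056), midgut and thorax muscle r = 0.78 (permutation p = 0.0014, adjusted 0.0049; rho = 0.78, p = 0.0046, adjusted 0.016), and male reproductive and thorax muscle r = 0.87 (permutation p = 6e-05, adjusted 0.00032; rho = 0.89, p = 0.00036, adjusted 0.0019). Without the 2 arrays farthest from the median of the first list of each pair, r was 0.91, 0.62 and 0.80. The midgut, male reproductive and thorax muscle lists were singled out after their common rise in the DD subjective night was seen. The 12 arrays include that rise, so these r and p-values are not separate evidence of joint movement. The permutations also treated the arrays as exchangeable, although they form a time series. Within the LD day alone, which did not define the pattern, r was 0.86, 0.23 and 0.48, and within the DD day 0.97, 0.89 and 0.93. Midgut and female germline medians had r = -0.07 (permutation p = 0.83, adjusted 0.95; rho = -0.24, p = 0.44, adjusted 0.84; r = -0.19 without the 2 farthest arrays). The first principal component of all probe sets held 45.9% of the variance, and its correlation with the score was r = 0.987 across the 12 arrays; the score was formed from genes that are themselves part of this component.

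**Figure D3:**
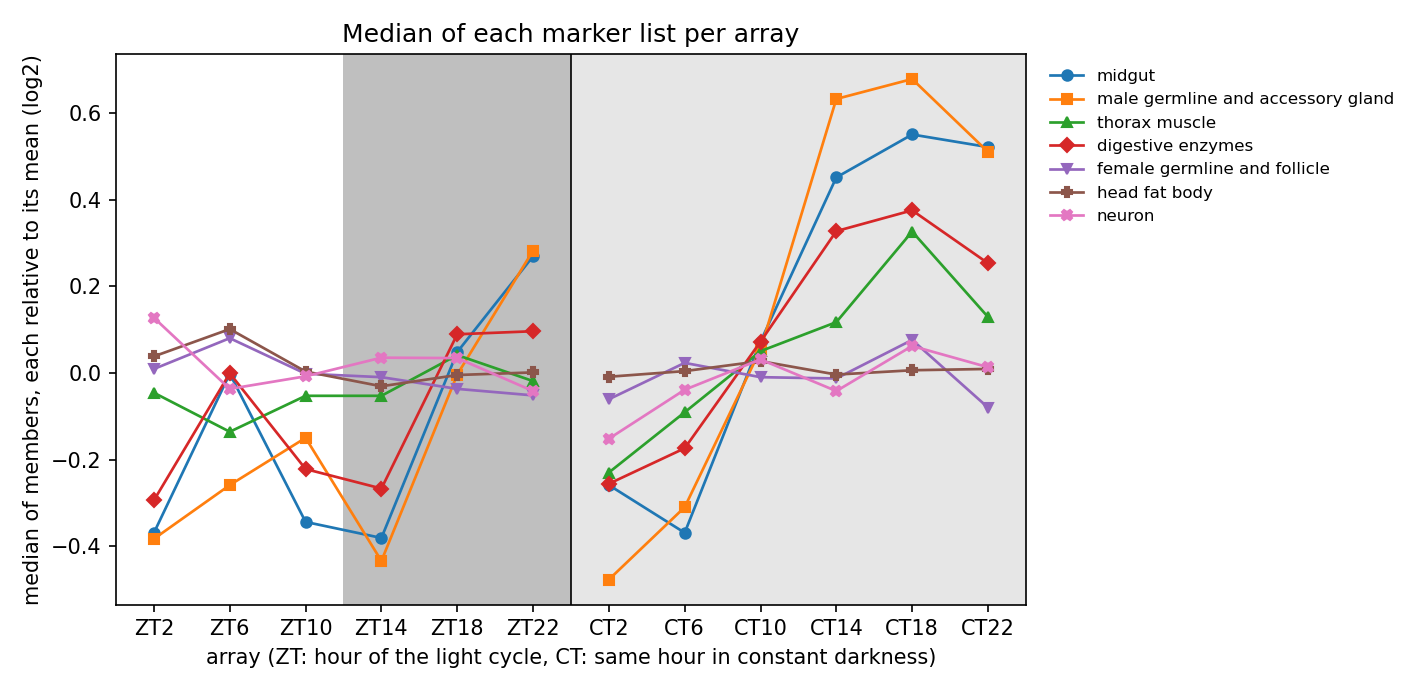
Median of each marker list per array (vertical axis, log2, each gene relative to its mean over the 12 arrays) against the array (horizontal axis); each point is 1 array, dark grey marks the dark phase of the LD day and light grey the DD day. The midgut, male reproductive and digestive lists lie highest at CT14, CT18 and CT22, where the body-tissue score was 0.39, 0.51 and 0.38, and the female germline, head fat body and neuron lists stay between -0.15 and 0.13 throughout.

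The 24 h harmonic in DD was called for 109 probe sets, and 16 of its 96 named genes were in the body-tissue or digestive lists. The protease gene Jon25Biii had an amplitude of 1.95 (SE 0.326, adjusted p = 0.0344) and the serpin gene Spn77Bb of 1.78 (SE 0.239, adjusted p = 0.0169; 0.94 for its other probe set, with adjusted p = 0.0169). They were followed by CG16904 (1.50), epsilonTry (1.47), the serpin gene Spn77Bc (1.46), Sgp (1.45), Acp36DE (1.44), the male ejaculatory duct peptide gene Anp (1.44), CG12861 (1.22), CG17097 (1.22), CG4363 (1.19) and the sperm gene Mst84Da (1.12). Their fitted peaks lay between hours 16 and 17.7. Harmonics passed for 7 of 24 male reproductive genes (21 over the list alone), 6 of 43 digestive enzymes (25), 3 of 14 midgut genes (10) and 3 of 17 thorax muscle genes (11). In the immune list, 0 of 24 genes passed, and 5 did over the list alone. Of 40 odorant binding protein genes, 1 passed, Obp56a (amplitude 0.49, adjusted p = 0.0366). Of 71 oxidative phosphorylation genes, 1 passed, COX4L (0.41, hour 15.9, adjusted p = 0.0294). The mean of COX4L, 2.46, lay below the lower quartile of every array. The score moved with the body-tissue and digestive lists. With it as a covariate the count was 12, of which 3 were among the 109. By permutation of the arrays within the day, which found 33 of 100 simulated amplitudes of 1, the count was 0; it was 20 with a trend over collection hours and also 20 above the median mean level, 66 with the trended robust prior, 174 with only the DD arrays, 0 without CT6 or CT14, 12 without CT2, 13 without CT18, 69 without CT10, 222 without ZT2 and 168 without ZT22.

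At the same clock hours in darkness, the LD dark phase and the DD subjective night differed in 28 probe sets, 6 higher and 22 lower in LD. Lower genes included Sgp (-1.57, SE 0.29), Act88F (-1.35, SE 0.228, adjusted p = 0.0266), Mal-A1 (-1.34, SE 0.192, adjusted p = 0.00762), CG4363 (-1.24), CG15219 (-1.10), CG8997 (-1.03), the testis gene tHMG1 (-0.99) and CG13323 (-0.95). Higher in LD were pkm (0.65, SE 0.121), the calcium exchanger gene Nckx30C (0.57, SE 0.108, adjusted p = 0.0484), CG1943 (0.54), CG9150 (0.54, SE 0.075, adjusted p = 0.0076) and CG11368 (0.36). Digestive enzymes had a median of -0.39, with 1 of 43 past the threshold and 29 over the list alone; male reproductive genes had -0.66 (0 of 24, and 20 over the list alone), midgut genes -0.60 (0 of 14, and 10) and thorax muscle genes -0.17 (1 of 17, and 6). Camera adjusted p-values for these 4 lists were 1.94e-07 or less, and with an estimated correlation adjusted p = 0.328 for the first 3 and 0.465 for thorax muscle. The body-tissue score differed by -0.46 between the groups, and with it as a covariate 0 probe sets passed. The 22 lower ones then had a median of -0.40 (median SE 0.15) in place of -0.83 (0.14), and all 22 kept their sign. Over all probe sets the standard error was larger by a median factor of 1.59 with the score. Without CT18 the thorax muscle median was -0.11. The count was 54 with median centring, 4 above the median mean level, 17 with only these arrays and 3 with clock hour as a block; it was 0 without CT18, 4 without CT14, 9 without ZT14 or ZT18, 13 without CT6, 18 without ZT2, 51 without CT2, 78 without CT10 and 184 without ZT22.

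Averaged over the whole day, LD and DD differed in 3 probe sets. Nckx30C was higher in LD by 0.50 (SE 0.076, adjusted p = 0.0417), with group means of 7.05 ± 0.13, 6.90 ± 0.18, 6.61 ± 0.19 and 6.33 ± 0.10 (SD, n = 3 each) from LD light to DD subjective night. CG15219 was lower by 0.66 on the log2 scale (-0.66, SE 0.101, adjusted p = 0.0417). The other was a probe set with no gene symbol, higher in LD by 0.60, which was mentioned after its values were seen. A second probe set of Nckx30C, with a mean of 5.19, differed by 0.04. Neuronal activity response genes, which include early transcription factors induced by firing, had a median of 0.10 (camera adjusted p = 0.018; adjusted p = 0.465 with an estimated correlation), and 4 of 13 were higher over the list alone. They included Hr4 at 0.27 (SE 0.062), CG14186 at 0.31 (SE 0.086) and sr at 0.23 (SE 0.063). Digestive, midgut, male reproductive and thorax muscle lists were lower in LD with medians of -0.23, -0.34, -0.36 and -0.06, and oxidative phosphorylation genes with -0.01 (camera adjusted p of 0.0377 or less for all 5; with an estimated correlation adjusted p = 0.404 or more). Without ZT22 or CT2 the neuronal activity list had adjusted p = 0.0515 and 0.0526. The oxidative phosphorylation call was lost without ZT2, ZT6, ZT14, CT2, CT10 or CT18, with adjusted p = 0.0526 to 0.43, and its median lay between -0.03 and 0.01 over the left-out arrays. The thorax muscle median was -0.03 without ZT6, -0.09 without ZT10, -0.11 without CT2 and -0.02 without CT10. The 3 calls became 0 with the body-tissue score as a covariate and above the median mean level, 83 without ZT22, and 1 with clock hour as a block or without any 1 of ZT2, ZT6, ZT14, ZT18, CT14, CT18 or CT22. They became 5 with quantile normalization (2 higher and 3 lower), 4 with median centring (1 higher and 3 lower), 14 with the trended robust prior and 7 with array weights.

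During the light hours, no probe set differed between LD and DD at the threshold. By limma 0 passed and 1049 had an unadjusted p under 0.05. The 5 genes with the smallest p-values each had adjusted p = 0.107. They were CG5455 (0.62, SE 0.094), the chaperonin subunit gene CCT8 (0.47, SE 0.077), Sirup (-0.40, SE 0.07), the protein disulfide isomerase family gene CaBP1 (0.41, SE 0.074) and Usp8 (0.79, SE 0.142). The 14 heat shock and chaperone genes had a median difference of 0.16 (camera adjusted p = 0.0022; adjusted p = 0.465 with an estimated correlation), and 1 was higher over the list alone. Its members with the smallest p-values were Hsp110 at 0.47 (SE 0.094, adjusted p = 0.182), Hsp26 at 0.19, Hsc70-2 at 0.21 and Hsc70-4 at 0.33 (SE 0.159). Neuronal activity response genes had a median of 0.10 (0.018; adjusted p = 0.465 with an estimated correlation), with sr at 0.32 (SE 0.09), glycolysis genes of 0.13 (0.0391; adjusted p = 0.66) and neuron genes of 0.09 (0.0444; adjusted p = 0.705), again with an estimated correlation. The body-tissue score differed by -0.02 between these groups. These list differences were not even over the light hours. Relative to each gene's own mean, the neuron median was 0.127 at ZT2 and -0.152 at CT2. It was -0.037 and -0.039 at hour 6, and -0.008 and 0.031 at hour 10, in LD and DD. At hour 10 the chaperone medians were -0.039 and -0.022 and the neuronal activity medians 0.005 and 0.003, whereas those of glycolysis were 0.042 and -0.004. The chaperone median was 0.10 without ZT2 and 0.11 without CT2, and without either of these arrays the neuronal activity list had adjusted p = 0.0741 and 0.0777 (0.16 without ZT10). The neuron median was 0.05 without ZT2 (adjusted p = 0.637) and 0.05 without CT2 (0.247), and the list had adjusted p = 0.123 without CT6. The glycolysis median was 0.08 without CT2 (adjusted p = 0.141), and the list had adjusted p = 0.093 without ZT2, 0.0898 without ZT10 and 0.189 without CT6. The gene count was 4 with clock hour as a block, 2 with the trended robust prior, 6 without ZT14 and 1 without ZT22 or CT6.

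Whether the day-night difference depended on the light cycle was tested as the difference between the LD and the DD contrast, and by limma 0 probe sets passed, with 1025 at an unadjusted p under 0.05. Sirup had the smallest adjusted p, 0.0694, with a difference of -0.69 (SE 0.1). Its group means were 7.93 ± 0.08 in LD light, 8.39 ± 0.10 in LD dark, 8.33 ± 0.07 in the DD subjective day and 8.10 ± 0.03 in the subjective night (SD, n = 3 each). The next genes were CG4377 (0.72), CG4363 (1.24), Mal-A1 (1.40) and CG13323 (0.86), each with adjusted p = 0.306. A second probe set of CG4377 was at -0.05. Over the list alone, 13 of 24 male reproductive genes and 1 of 43 digestive enzymes passed, and 0 of each over all probe sets. The count was 1 above the median mean level, with the trended robust prior or with array weights, 3 with a trend over collection hours, 2 without ZT14 or CT10 and 6 without ZT22.

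A curve common to both days was called for 1 gene. Obp56a (CG11797), an odorant binding protein gene, had an amplitude of 0.48 (SE 0.056, adjusted p = 0.0334) with a peak at hour 2.2. Its value was 4.83 at ZT2 and 4 at ZT18, and 4.90 at CT2 and 3.83 at CT18. Of 40 odorant binding protein genes, 1 passed and 5 did over the list alone. Without a threshold pass over all probe sets, 14 of 24 male reproductive, 9 of 43 digestive, 9 of 17 thorax muscle and 4 of 31 phototransduction genes passed over their lists alone. The count became 0 with quantile normalization, with a trend over collection hours, by permutation within days, and without any 1 array other than CT14; it became 2 without CT14 and 2 with the body-tissue score as a covariate.

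Of the 28 lists, 12 were called by camera in at least 1 contrast and 16 in none. In the DD subjective day, glycolysis genes were lower than in the subjective night with a median of -0.16 (0.00614), while cytosolic ribosomal proteins were higher with 0.08 (0.0122) and cuticle proteins with 0.03 (0.0356). With an estimated correlation these had adjusted p = 0.505, 0.705 and 0.724. In that contrast the body-tissue score differed by -0.61, and the glycolysis median was lowest at CT2, at -0.18, where the score was also lowest. The glycolysis median was -0.09 without CT2, and without CT6 the list had adjusted p = 0.0572. The ribosomal list had adjusted p = 0.45 without CT2 and 0.339 without CT14, with medians of 0.05 and 0.04. The cuticle list had adjusted p = 0.0506, 0.0928, 0.222 and 0.103 without CT2, CT6, CT18 or CT22, and its median was 0.07 without CT14. The 16 lists without a call were core clock, clock output candidates, phototransduction and visual cycle, screening pigment, DNA repair and photolyase, antimicrobial and immune response, fasting and feeding response, fatty acid and sterol synthesis, detoxification, proteasome, odorant binding proteins, neuropeptides, glia, female germline and follicle, sex marker, and hemocyte. Their medians lay between -0.12 and 0.13 over the 6 contrasts, and their smallest camera adjusted p was 0.0562. In the 6 contrasts, the members of these 16 lists past the threshold were PGRP-SC2, which encodes a peptidoglycan recognition protein, at -0.46 (SE 0.107, adjusted p = 0.0468) in the DD contrast, and the fatty acid synthase gene FASN2 at -0.56 (SE 0.107, adjusted p = 0.0162) in the same contrast. Changes in either direction, tested with fry's mixed test, which does not compare a list with other genes, passed for 4 lists in the LD contrast. They were phototransduction and visual cycle (adjusted p = 0.00462), head fat body (0.00532), screening pigment (0.024) and detoxification (0.0464). That test passed for 4 lists in the DD contrast, 1 in their difference, 4 in light against darkness, and 10 each in dark against dark and LD against DD, and its smallest adjusted p was 0.000146, for screening pigment in LD against DD.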

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

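All tests of explanations below were chosen after the results they weigh had been seen, and the body-tissue score as a covariate was also added then.

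The test of the difference between the LD and the DD contrast singled out 6 gene lists by camera. The medians were 0.17 for heat shock and chaperones (adjusted p = 0.0055), 0.353 for digestive enzymes (1.23e-10), 0.182 for glycolysis (0.00462), 0.157 for thorax muscle (0.000495), 0.525 for midgut (2.6e-06) and 0.61 for male germline and accessory gland (3.36e-12). With an estimated correlation the adjusted p-values were 0.481, 0.465, 0.505, 0.505, 0.465 and 0.465, so none of the 6 differences held there. The chaperone median was 0.103 without ZT2 and 0.088 without CT2, and that of thorax muscle was 0.077 without CT2.

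Transcripts of the midgut, male reproductive and thorax muscle lists were higher in the DD subjective night. The scale of the arrays was excluded as the whole cause, since 160 of the 194 probe sets were also called after quantile normalization. Tissue of other body parts carried into the head preparations may account for the pattern but was not established: the lowest correlation among the 3 marker lists, 0.78 over the 12 arrays, includes the difference in question and was 0.23 within LD. The highest members went from 7.03 to 9.88 (betaTry), 5.03 to 7.84 (Acp95EF) and 9.99 to 10.28 (Mlc2), although heads had been separated with sieves and the female list moved by 0.005. With the score as a covariate the 187 lower probe sets had a median of -0.16 (median SE 0.18) in place of -0.82 (0.14), 144 kept their sign, and the call ended with both the smaller difference and a standard error larger by a factor of 1.91 over all probe sets. A daily rhythm in darkness, in heads or elsewhere, also stays open, because the exact permutation p of the score, 0.1, is the smallest that 3 arrays against 3 allow and there was 1 cycle.

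The chaperone list had a median of 0.162 in the LD light phase against the same hours in DD, a camera call lost with an estimated correlation (adjusted p = 0.465), and 0 of its 14 genes passed over all probe sets. Tissue of other body parts was not tested by the body-tissue covariate, with which the median was also 0.162, because the score differed by only -0.02 there and could not move it. The CT2 array had the lowest median level, and without it the list median was 0.107. This value lay between the bounds set for a cause and for no cause. The median was also 0.1 without ZT2, so the drop is not particular to CT2. Leaving an array out does not test its level by itself. The camera call was kept with median centring and with quantile normalization, which even out the levels of the arrays. This argues against the lower level of CT2 as the cause of the call. Light itself stays open, because between the light and the dark phase of the LD day the list had a median of 0.082 and a camera adjusted p of 0.0686, and the order of the days cannot be told apart from light.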

How the results depend on the processing

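The body-tissue score as a covariate and the fits without the 3 subjective-night arrays were added after the data were seen; the other alternatives were planned. Where no cause is named, the cause was not tested. For light against dark in LD (4 probe sets), counts were 0 with quantile normalization, with a trend over collection hours, with only the arrays compared and without the subjective-night arrays, 9 with the trended robust prior, 7 with array weights and 5 with median centring (1 higher, 4 lower). For subjective day against night (194), they were 82 above the median mean level, 101 with the trended prior, 0 with the trend, 293 at a threshold of 0.10 and 0 with the body-tissue score. For the difference of both contrasts (0), they were 1 above the median mean level, with the trended prior, with array weights and at 0.10, and 3 with the trend. For light against darkness (0), they were 2 with the trended prior and 4 with clock hour as a block. For dark against dark (28), they were 54 with median centring, 4 above the median mean level, 105 at 0.10, 17 with only the arrays compared, 3 with the block and 0 with the score. For LD against DD (3), they were 5 with quantile normalization, 4 with median centring, 0 above the median mean level, 14 with the trended prior, 7 with array weights, 17 at 0.10, 1 with the block and 0 with the score. For the LD harmonic (9), they were 4 with quantile normalization, 16 with median centring, 28 above the median mean level, 38 with the trended prior, 23 with array weights, 34 at 0.10, and 0 with only that day, without the subjective-night arrays and by permutation. For the DD harmonic (109), they were 20 above the median mean level, 66 with the trended prior, 20 with the trend, 211 at 0.10, 174 with only that day, 12 with the score and 0 by permutation. The permutation test recovered few simulated amplitudes of 0.5 within a day (4 of 100 in LD), so its 0 for LD says little. For the shared harmonic (1), they were 0 with quantile normalization, with the trend and by permutation, and 2 with the score. Of 32 list calls, 0 held with an estimated correlation, 0 by fry, and the score gave 7, of which 3 were among the 32. Larger counts at 0.10 follow from the threshold, and fits of fewer arrays had fewer residual degrees of freedom. Leaving out 1 array at a time gave counts of 0 to 8 (LD contrast), 34 to 254 (DD contrast; 34 without CT2, 40 without CT6, 72 without CT14, 44 without CT18), 0 to 6 (difference), 0 to 6 (light against darkness; 6 without ZT14), 0 to 184 (dark against dark; 184 without ZT22, 0 without CT18), 1 to 83 (LD against DD; 83 without ZT22), 3 to 15 (LD harmonic), 0 to 222 (DD harmonic; 0 without CT6 or CT14, 222 without ZT2), 0 to 2 (shared harmonic) and 26 to 43 (lists). With the score as a covariate the DD differences turned positive for Jon99Fi (0.418), alphaTry (0.818), betaTry (0.98), yip7 (0.923), Jon25Biii (0.449), Bace (0.661), Acp53C14a (1.03) and Jon99Fii (0.384). The DD harmonic moved its peak by more than 6 h for Jon25Biii (amplitude 0.415), CG16904 (0.299), Spn77Bc (0.434), Anp (0.555) and Mst84Da (0.177). List medians turned positive for digestive enzymes (0.085) and midgut (0.052) in the DD contrast, for digestive enzymes (0.038), midgut (0.042) and male reproductive genes (0.017) in dark against dark, and for digestive enzymes (0.021) and thorax muscle (0.01) in LD against DD. The score is built from the midgut, male reproductive and thorax muscle medians, and 11 of the 14 midgut genes are digestive enzymes, so values near 0 for these lists follow in part from its construction. Counting each named gene once per comparison, 17 kept direction and side of the threshold with the score, 32 lost the threshold and 13 turned; with quantile normalization 46 kept both and 16 lost the threshold. The trend was not fitted to contrasts between days, and a different log offset was not run because the values were already log2. Within a day the trend is partly confounded with the phases, so lower counts with it cannot tell a steady change from a daily one. Signal over background was not given in the table used here, so the limit set by low signal was examined only through the filter on mean level.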

Other observations

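The tests of explanations and the counts of other arrangements below had their predictions written after the results were seen, and these tests and the difference of the harmonic between days were chosen then.

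Apart from PGRP-SC2 in the DD contrast, immune and pigment genes did not pass over all probe sets in the contrasts. In the DD harmonic, 5 of 24 antimicrobial and immune genes passed when adjusted over the list alone, with the smallest p-values for the secreted peptide gene BomS2 (amplitude 0.37, SE 0.068, adjusted p = 0.0525 over all probe sets), the peptidoglycan recognition gene PGRP-SB1 (0.34, SE 0.075), PGRP-SC2 (0.33, SE 0.078) and the antifungal peptide gene Drs (0.58, SE 0.141). In the light phase of LD against the same hours in DD, PGRP-LB, which encodes an enzyme that degrades peptidoglycan, was at 0.34 (SE 0.068, adjusted p = 0.182). Of 19 screening pigment genes, 2 were higher and 2 lower there over the list alone, with ry, the xanthine dehydrogenase gene, at -0.37 (SE 0.092) and se at -0.29 (SE 0.078). Of 11 clock output candidates, 2 were higher and 2 lower, with CG2121 at 0.77 (SE 0.222) and Achl at -0.33 (SE 0.091).

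Some control probe sets set ZT14 apart. The difference between the 3′ and 5′ probe sets of eIF-4a was 3.70 at ZT14 and lay between 2.90 and 3.33 on the other 11 arrays, and that of GAPDH was 2.58 at ZT14 and 2.10 to 2.42 elsewhere. That of actin was 2.30 at ZT14, inside the range of 1.95 to 2.52 of the others. The mean of 9 spike-in probe sets was 8.32 at ZT14 and 8.84 to 9.28 elsewhere.

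The 7 named genes with a 24 h harmonic in LD had smaller amplitudes in DD, from 0.047 (Lsp2) to 0.144 (CG7135), none past the threshold. They were picked for passing in LD, which by itself favours larger amplitudes there. With the body-tissue score as a covariate the median ratio of amplitudes was 1.03. For t, Slob, Drat and lqf, 4 of the 7, tissue marked by the score was not the whole cause, since they stayed past the threshold. Lsp2, rdhB and CG7135 lost the threshold (limma adjusted p = 0.0831 each), but their amplitudes were 0.428, 0.38 and 0.311 in place of 0.484, 0.391 and 0.345. The score ranged more widely in DD, from -0.332 at CT2 to 0.508 at CT18, than in LD, from -0.3 at ZT14 to 0.167 at ZT22. In DD the amplitudes of Lsp2, rdhB and CG7135 were only 0.047, 0.067 and 0.144. These values argue against tissue marked by the score as the whole cause for these genes. The score covers midgut, male reproductive and thorax muscle markers, so other tissue, such as fat body, was not tested. A single array did not carry the amplitudes of the 7 genes as a set, because the lowest median ratio without 1 LD array was 0.98. Still, 2 of the 7 stayed past the threshold without ZT6, ZT14 or ZT18. A median over genes with different peaks cannot exclude a single array for each gene. The amplitude of Slob, 0.595 with all arrays, was 0.491 without ZT6 and 0.71 without ZT22. Whether the light cycle drives these changes stays open, because the smallest adjusted p of the difference was 0.13 and the light cycle cannot be told apart from the day of collection.

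Counts were also taken under other arrangements of the arrays. For the contrasts of 3 arrays against 3, the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 4 and 2 for light against dark in LD (1 split as large), 194 and 0 for subjective day against night (1), 0 and 1 for light against darkness (10), and 28 and 0 for dark against dark (1). For LD against DD, 3 of 100 splits gave a count as large as the real 3, a share under 0.05 for this 1 of 9 counts without allowance for the number of counts, and the highest other gave 28. For the difference of both contrasts the real count was 0, so 100 of 100 splits were as large, and the highest gave 215. That split had a body-tissue score difference of 0.88, against 0.44 for the real one, and 0 splits had a larger one, but the rank correlation of count and score difference over the splits was 0.32. For LD against DD it was 0.1. For the harmonics, 4 of 60 orders of the LD arrays gave a count as large as 9 (highest other 29), 4 of 60 orders of the DD arrays one as large as 109 (highest other 170), and 5 of 100 orders one as large as the shared count of 1 (highest other 12), so chance was not excluded for these 3 counts. Some arrangements gave several times the real count, and what sets them apart was not identified.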
